A study of Mus musculus with 8 samples.

How the data were processed

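Spinal cord myeloid cells of naive mice, mice 1 week after spinal cord injury (SCI) and mice at peak EAE were sequenced on the BD Rhapsody system, after papain digestion, myelin removal and positive selection with CD11b beads, per the labels' protocols. The authors deposited 1 table of raw counts per gene and cell, and an annotation that gives each cell its pool, condition, genotype and sample tag. The values were checked to be whole, non-negative and equal in sum to the annotated totals, and 90.98% of entries were 0. STAR (version not given) and the mm10 genome come from the submitters' processing notes. The counter, the cell filter and the calling of sample tags are not given in the sources used here. Of 26470 gene names, 1584 were changed back from an altered form, and 25341 then matched GENCODE M21 (GRCm38, the mm10 genome), which gave the positions and identifiers.

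The 8 GEO samples are transcriptome and tag libraries of 3 pools. The 47860 cells belong to 12 tagged samples with 8443187 to 66123312 counts each and medians of 4115 to 9497 counts per cell. Intervals on single levels are exact Poisson or Clopper-Pearson intervals at 95%, and cover counting error only. Each Trem2-deficient sample (TM2 or CreTM2) was paired with the control (WT or Cre) of the same condition and line, as read from the annotation. In SCI and EAE this is also the same pool, while all naive samples share 1 pool. This gave 6 pairs, 2 per condition. The pairing was checked by whether pair members deviate together from their group means, across genes. In microglia the correlation was 0.135 in naive, 0.686 in SCI and -0.243 in EAE samples, and in monocytes and macrophages 0.695 in SCI and -0.123 in EAE samples. For SCI against EAE it was 0.132 to 0.481 in microglia and 0.0552 to 0.435 in monocytes and macrophages. The SCI and EAE pairs were kept whatever these values, since they come from the pools. Naive samples were fitted without pairs within their condition.

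No deposited annotation named cell types, so cells were clustered with scanpy 1.11.5 and leidenalg 0.10.2. Counts were scaled to 10000 per cell and log-transformed, with 2000 variable genes, 30 components, 15 neighbours, resolution 1 and seed 0. The 27 clusters were joined to 8 classes by marker genes fixed before the data were examined, and clusters 6 (low counts, Mbp and mitochondrial genes), 10 (microglial and monocyte markers together) and 18 (cell cycle genes, mixed markers) stayed unnamed. Scrublet, as built into scanpy, called 0 doublets among 8293, 16491 and 23076 cells of pools A, B and C, so it failed as a filter and no cell was left out. Clusters of mixed markers may hold doublets.

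Counts were summed per tagged sample and class (at least 20 cells) and tested with edgeR 4.0.16 (filterByExpr, TMM, quasi-likelihood F test, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3. The fits covered Trem2 loss over all pairs with pair as a factor, and within each condition with pool as a factor, except in naive samples, which share a pool. They also covered the interactions of Trem2 loss with condition and with line, SCI against EAE paired by genotype, and SCI and EAE against naive paired by genotype. Shares were tested by an exact two-sided sign-flip permutation over pairs. Ratios of single pairs added 5 CPM to each level. Shares of cells with a count used cells thinned to 3000 counts, which left out 290 to 1125 cells per sample.

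Gene lists were tested with camera and fry of limma 3.58.1, camera with a preset correlation of 0.01 and again with an estimated one. With an estimated correlation camera uses only the residual degrees of freedom of the fit, 1 to 5 here. Few lists could pass on so few, so a call lost there does not by itself show correlated genes. Of fry only the test of direction is reported, while its test of change in either direction was run and is not given. The 16 lists were homeostatic microglia, the Trem2-dependent and the Trem2-independent stage of damage-associated microglia, lipid uptake, storage and efflux, cholesterol synthesis, phagocytosis and lysosome, type I interferon response, MHC class II, inflammatory cytokines and chemokines, alternative activation and repair, complement, proliferation, glycolysis, oxidative phosphorylation, immediate early genes and hypoxia. A list of sex-linked genes served to check the pools. Genes named in the text were those called with the same direction in every pair, up to 12 with the largest change each way, with Trem2 and Tyrobp always and up to 4 members of each list that camera called. Tests of list members are given over all genes and adjusted over the list alone.

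The fits were tested on simulated counts with 200 changed genes. Each simulated change had the same size in every pair, and the spread followed its trend over genes. The simulation thus holds no difference of effect between pairs, and its shares do not show that a real 2-fold change would be called. Trem2 loss over all pairs recovered 99% of 2-fold and 100% of 4-fold changes in microglia (12153 genes, 7 false calls) and 88% and 99% in monocytes and macrophages (11966 genes, 2 false calls). Within naive microglia the shares were 91% and 99% (11137 genes, 12 false calls), within SCI 90% and 100% (12005 genes, 14) and within EAE 20% and 95% (11432 genes, 5). SCI against EAE gave 94% and 100% in microglia (12052 genes, 7) and 92% and 99% in monocytes and macrophages (11846 genes, 10), and SCI against naive 69% and 95% (11702 genes, 4).

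Alternatives were DESeq2 size factors in the edgeR fit, no filter on low counts, the DESeq2 1.42.0 Wald test, no pair factor, each pair left out in turn, at least 50 cells per sample, cells thinned to 3000 counts, 1 line alone, other offsets (1 and 20 CPM), another denominator of shares and the estimated correlation. Others were chosen after seeing the data: leaving out the 5% of cells with most counts or single clusters, spread pooled over the conditions, all 4 genotypes against naive, and most alternatives within each condition. Naive pairs were also fitted with pair as a factor. Tables and figures used scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.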

Results

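Spinal cord cells bound by beads against the myeloid surface protein CD11b were profiled by single-cell RNA sequencing on the BD Rhapsody platform. The mice (C57BL/6 by the labels of pools A and B) were naive, 1 week after spinal cord injury (SCI), or at the peak of experimental autoimmune encephalomyelitis (EAE), a T cell driven disease of the spinal cord. The cell annotation gave 4 genotypes per condition. WT and TM2 (Trem2-/-) formed one line, and Cre (used here as the control, while the titles of pool C say WT) and CreTM2 (Cx3cr1CreER:Trem2fl/fl, loss of Trem2 in cells that express Cx3cr1) formed the other. These made 12 tagged samples in 3 pools, since cells carried sample tags and were mixed before capture. Pool A held the 4 naive samples, pool B the SCI and EAE samples of WT and TM2, and pool C those of Cre and CreTM2. The count table held 47860 cells and 26470 genes. Cells per tagged sample ran from 1648 in naive CreTM2 to 7238 in EAE Cre, and total counts from 8443187 to 66123312 in the same samples. The median count per cell ran from 4115 in naive Cre to 9497 in SCI WT. Each Trem2-deficient sample was paired with the control of its own condition and line, which gave 6 pairs. The labels of pool A name only WT and Trem2-/- animals, so its Cre and CreTM2 samples rest on the cell annotation. By the labels the samples of pools A and B mix at least 2 animals each, and no label says which samples were prepared apart, so p-values here measure only the spread between these samples.

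Trem2 codes for a lipid-sensing receptor of microglia and macrophages, and its level checked the genotype labels first. The gene (ENSMUSG00000023992) lies on chromosome 17 of the mm10 genome, from 48346401 to 48354147. In naive microglia Trem2 was at 1286 CPM (counts scaled to one library size) in WT (95% exact Poisson interval 1264 to 1308) and 217 in TM2. It was at 1347 CPM in naive Cre and 310 in naive CreTM2. In SCI microglia it was at 2199 CPM in WT and 499 in TM2, and at 2130 in Cre and 1254 in CreTM2. In EAE microglia it was at 787 CPM in WT and 464 in TM2, and at 1300 in Cre and 622 in CreTM2. Trem2 was thus lower than its control in all 6 pairs, by a mean log2 ratio of -1.56 (SD 0.789, n = 6). The log2 ratio ran from -2.54 in the naive TM2 pair to -0.76 in the SCI CreTM2 and EAE TM2 pairs.

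In monocytes and macrophages Trem2 fell in the SCI TM2 pair from 1981 to 547 CPM, but in the SCI CreTM2 pair it was 2038 and 1888 CPM, a log2 ratio of -0.11. In EAE the same cells held 403 CPM in WT and 266 in TM2, and 726 in Cre and 697 in CreTM2. The log2 ratio of that CreTM2 pair was -0.06, and -0.355 at an equal 3000 counts per cell. Every Trem2-deficient sample kept Trem2 counts. The labels do not say which part of the gene was removed, and reads from a part left in place would still be counted. At an equal 3000 counts per cell, 58.6% of SCI TM2 microglia had a Trem2 count (1237 cells; 73.3% of 1346 cells unthinned, median depth 5971), against 98.0% of SCI WT microglia (1513 cells; 98.7% of 1583 unthinned, median depth 8601). Neutrophils, which should lack the gene, had one in 41.2% of cells in SCI TM2 (170 cells, median depth 6520). In SCI WT it was 68.8% (157 cells, median depth 8520.5). Part of these shares may thus be RNA of other cells, and free RNA, doublets and wrong tags were not told apart.

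**Figure D1:**
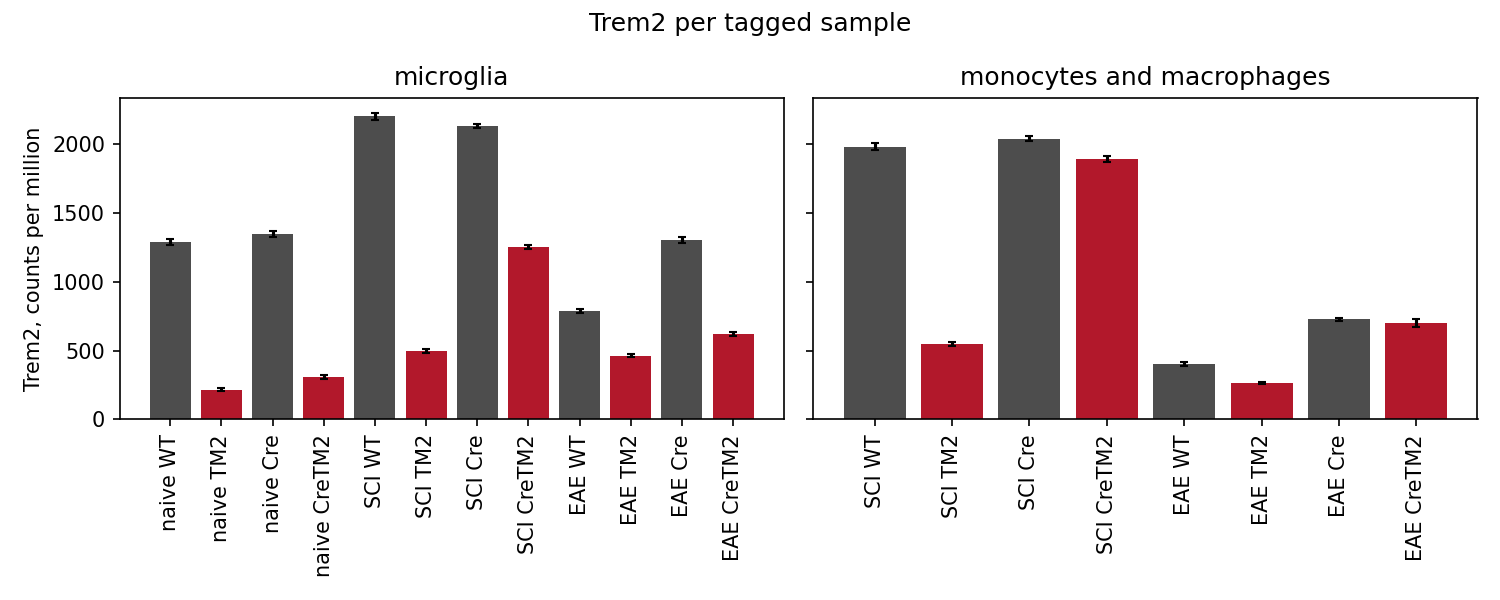
Trem2 in CPM (y axis) in each tagged sample (x axis), for microglia on the left and for monocytes and macrophages on the right. Grey bars are controls, red bars are Trem2-deficient samples, and error lines are 95% exact Poisson intervals. In microglia every red bar is lower than the grey bar to its left, from 1286 to 217 in the naive WT and TM2 pair.

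Clustering gave 27 clusters, named from marker genes as cells like microglia, monocytes and macrophages, border-associated macrophages, neutrophils, dendritic cells, lymphocytes or other cells. All shares are of cells kept by the CD11b selection. Cluster 8, which held 18.1% to 25.4% of naive cells, was counted as microglia, though Mbp, Mobp, Plekhb1, S100b and Bcas1, genes of myelin and other glia, were among its top 10 genes beside P2ry12, Selplg, Tmem119 and Cx3cr1. Microglia made up 71.3% to 79.5% of cells in the 4 naive samples and 43.2% to 50.2% in the SCI samples. In EAE they made up 35.1% in WT, 18.02% in TM2, 15.9% in Cre and 60.6% in CreTM2. Monocytes and macrophages made up under 1% of each naive sample, 24.7% to 31.4% of the SCI samples, and 24.9%, 71.7%, 48.6% and 11.9% of EAE WT, TM2, Cre and CreTM2. Clusters kept out of every class held 3.82% to 5.21% of naive, 7.34% to 15.1% of SCI and 5.95% to 28.3% of EAE cells. One of them, cluster 10, left unnamed for microglial and monocyte markers in the same cluster, held 24.5% of EAE WT. Whether single cells carried both was not tested.

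With Trem2 loss no class share passed an exact two-sided sign-flip permutation test over the 6 pairs. The smallest p came from border-associated macrophages, which carry Mrc1, Cd163 and Lyve1. Their share was higher with Trem2 loss in 5 of 6 pairs, by a mean of 2.56 percentage points (SD 1.95), with an exact p = 0.0625 (adjusted p 0.5 over 8 classes). The smallest p that 6 pairs allow in this permutation test is 0.0313 before adjustment. A single changed class could thus not pass after adjustment over 8 classes. The EAE pairs moved in opposite directions. Microglia were 17.1 points lower in TM2 than WT (the difference was -17.1) and 44.7 points higher in CreTM2 than Cre. Monocytes and macrophages differed by 46.8 and -36.7 points. Cluster 10, left out of every class, held 24.45% of EAE WT and 2.754% of EAE TM2 cells. The differences of the EAE TM2 pair thus depend on where this cluster is counted. Without the EAE CreTM2 pair the mean difference for microglia was -5.56 in place of 2.81 points. Without the EAE TM2 pair that for monocytes and macrophages was -8.15 in place of 1.001 points.

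**Figure D2:**
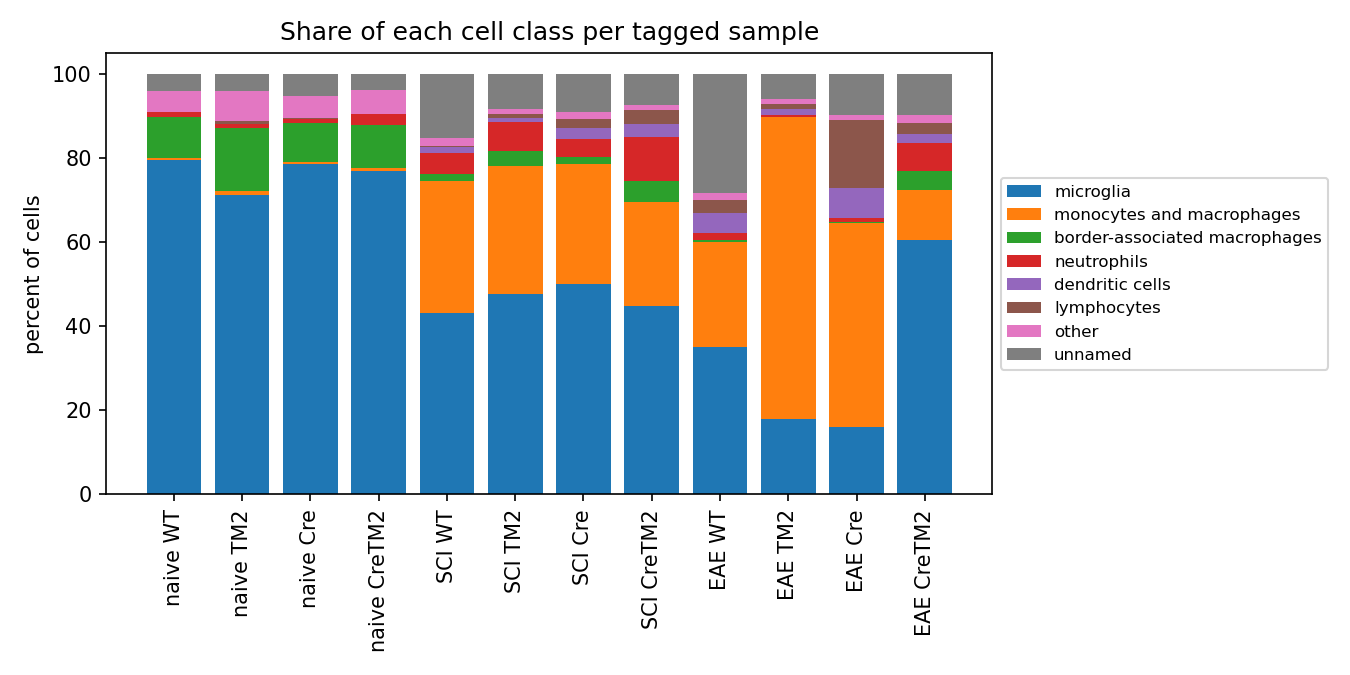
Percent of cells (y axis) in each class, stacked by colour, for the 12 tagged samples (x axis). Microglia fill 71.3% to 79.5% of the naive samples, and the 4 EAE samples differ among themselves from 15.9% to 60.6%.

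The first question was which microglial genes depend on Trem2 across all 6 pairs. Lpl, which codes for a lipase of lipid uptake, averaged 508 ± 495 CPM in controls and 193 ± 220 with Trem2 loss (SD, n = 6), a log2 change of -1.63 (SE 0.320). Itgax, Spp1 and Ch25h, genes of the damage-associated microglial state, had log2 changes of -1.41 (SE 0.335), -1.29 (SE 0.350) and -1.14 (SE 0.221). Klf2 and Fosb, genes induced by stress and dissociation, each had a log2 change of 0.41. Each of these, named as a list member of large change, moved the same way in 6 of 6 pairs, while Siglech, another, rose in 5 of 6. With edgeR's quasi-likelihood test none passed adjustment over 12302 genes. The adjusted p was 0.277 for Trem2, 0.410 for Lpl and 0.487 for Spp1, and that for Tyrobp, the signalling partner of Trem2, was 0.883 with a log2 change of -0.08.

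The count of genes called in microglia over the 6 pairs was thus 0, with 978 genes at an unadjusted p under 0.05. DESeq2 called 29 genes, 4 of them up and 25 down. Without the EAE TM2 pair edgeR called 66 genes, all down. Of the 19 tested members of the Trem2-dependent damage-associated list, none was called over all genes, and 8 fell when adjusted over the list alone. The list had a median log2 change of -0.40, and 19 of 19 members had a negative change. With its preset correlation the set test camera called 10 of 16 lists. The adjusted p was 9.18e-18 for that list (down), 1.6e-08 for homeostatic microglia (up) and 1.33e-09 for proliferation (down). None of the 10 held with an estimated correlation (adjusted p 0.371 for each of these 3 lists), and fry called none (smallest adjusted p 0.249). The alternative activation list had a positive median and mean (0.06 and 0.03) where camera gave the direction down.

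In monocytes and macrophages, which in the adult come from blood, 4 SCI and EAE pairs could be compared. In the CreTM2 pairs the log2 ratios of Trem2 in these cells were -0.11 in SCI and -0.06 in EAE. Those of the TM2 pairs were -1.85 and -0.59. With cells thinned to equal depth the CreTM2 pairs had -0.115 and -0.355, and the TM2 pairs -1.836 and -0.546. The SCI CreTM2 pair thus showed hardly any loss of Trem2, while the size of the loss in the EAE CreTM2 pair changed with thinning. What follows therefore compares the samples by genotype and not by loss of the transcript. Cst7, a protease inhibitor gene of the damage-associated state, averaged 74.9 ± 25.8 CPM in controls and 52.89 ± 15.97 in the TM2 and CreTM2 samples (SD, n = 4). Il1b, an inflammatory cytokine gene, averaged 2654 ± 2497 and 2123 ± 2097 CPM. Their log2 changes were -0.47 (SE 0.179) and -0.51 (SE 0.175), negative in 4 of 4 pairs. Trem2 itself had a log2 change of -0.66 (SE 0.288) and Tyrobp one of 0.07. All had an adjusted p of 1.0 with edgeR, which called 0 of 12129 genes, with 288 at an unadjusted p under 0.05. DESeq2 called 1 gene. Camera called 9 of 16 lists with its preset correlation and 0 with an estimated one (smallest adjusted p 0.357), and fry called 0. The call of lowest adjusted p was a fall of glycolysis (median log2 change -0.22, adjusted p 8.82e-10, and 0.357 with an estimated correlation). For alternative activation the median was 0.00 and the mean -0.08, and for phagocytosis both were negative (-0.00 and -0.02) where camera gave the direction up.

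Within the naive condition, where microglia were unchallenged, 8 genes fell and none rose among 11309 tested (edgeR, 2 samples per arm). With the pair as a factor 6 rose and 52 fell, and DESeq2 called 15, all down. Besides Trem2 (log2 change -2.34, SE 0.128, adjusted p 3.94e-05) these were Spp1, Itgax, Cst7, Apoe, Cd52, Cd63 and Mt1. Spp1, which codes for osteopontin, averaged 20.3 ± 6.03 CPM in controls and 2.31 ± 0.687 in deficient samples (SD, n = 2), with a log2 change of -3.19 (SE 0.290, adjusted p 0.0015). Apoe, the main lipid carrier gene, fell from 508 ± 41.6 to 238 ± 23.1 CPM, a log2 change of -1.10 (SE 0.091, adjusted p 0.000793). Itgax fell by 2.11 and Cst7 by 1.45 on the log2 scale. Lpl (log2 change -2.26, adjusted p 0.0642) and the chemokine gene Cxcl2 (-0.98, adjusted p 0.0534) did not pass, and Tyrobp was at 1429 and 1436 CPM.

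The 8 naive genes fell in both pairs. Of 19 tested members of the Trem2-dependent list, 5 fell over all genes and 13 fell when adjusted over the list alone. The inflammatory list had 0 calls over all genes, and 9 of 18 members fell and 1 rose when adjusted over the list alone. Camera called 7 lists. The Trem2-dependent list had an adjusted p of 1.38e-56, which was 0.052 with an estimated correlation, and no list held with it. The estimate for the Trem2-dependent list was -0.025, below the preset 0.01. Its call was thus not lost to a higher correlation, and that test had 2 residual degrees of freedom. Fry called 1 list, lipid uptake, storage and efflux (adjusted p 0.00203), in which Apoe was the 1 member called. The alternative activation list had a median of 0.03 and a mean of -0.01. With a spread pooled over the conditions 0 genes were called, at log2 changes of -2.36 for Trem2, -3.15 for Spp1 and -1.11 for Apoe. The pooled spread takes in that of EAE, which was wider (edgeR common dispersion 0.0677, against 0.00412 within naive microglia). Leaving out either naive pair left 1 sample per arm, so no count is given for it. Without the 5% of cells with most counts 7 genes were called. Spp1 then had a log2 change of -2.08 in place of -3.19 (adjusted p 0.499), and Cd63 one of -0.47 in place of -0.57 (adjusted p 0.104). Cluster 1, with Lpl, Spp1 and Apoe among its top genes, held 0.215% of naive WT and 0.26% of naive Cre cells. It held no naive TM2 or CreTM2 cells. No naive fit without cluster 1 was run, so it stays open how far a few such cells carry these falls.

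In SCI microglia 304 genes rose and 386 fell with Trem2 loss among 12161 tested (edgeR, 2 pairs). Spp1 averaged 6075 ± 3397 CPM in controls and 2938 ± 1904 with loss (SD, n = 2), a log2 change of -1.13 (SE 0.110, adjusted p 7.26e-05). Lpl fell from 1124 ± 110.0 to 400 ± 303 CPM, a log2 change of -1.75 (SE 0.291, adjusted p 0.00283). The receptor gene Axl, the scavenger receptor genes Cd36, Msr1 and Olr1, the matrix genes Fn1 and Mmp12 and the growth factor binding gene Igfbp5 fell by 0.77, 1.42, 0.84, 1.94, 2.04, 1.76 and 2.41 on the log2 scale. The cytokine genes Il1b and Cxcl1 fell by 1.17 and 1.33. P2ry12, a marker of resting microglia, averaged 470 ± 7.56 CPM in controls and 858 ± 10.5 with loss, a log2 change of 0.83 (SE 0.091, adjusted p 0.000172), Siglech changed by 0.78, and Slc2a5, a fructose transporter gene, by 1.42. The interferon-induced genes Ifit3, Ifit1 and Rsad2 rose by 1.25, 1.10 and 1.48. Jun and Hspa1a, genes induced during dissociation, rose by 0.68 and 0.79.

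In SCI microglia 10 of 18 homeostatic genes rose and none fell (13 rose when adjusted over the list alone). Of 20 interferon genes 12 rose (17 over the list alone), and of 19 immediate early genes 9 rose (15). Of 19 Trem2-dependent genes 11 fell (15), and of 8 in the Trem2-independent stage none was called. Of 20 lipid genes 7 fell and 1 rose, of 21 inflammatory genes 8 fell and 2 rose, of 24 phagocytic and lysosomal genes 4 fell, and of 16 glycolytic genes 7 fell (11). Cholesterol synthesis, proliferation and oxidative phosphorylation had 3, 3 and 2 members that fell, and the 10 genes of MHC class II none that changed. Alternative activation had 2 up and 5 down, with a median of -0.11 and a mean of 0.03. Complement had 1 up and 2 down, and hypoxia 1 up and 3 down. Camera called 11 lists with its preset correlation, none of which held with an estimated one (adjusted p 0.49 or more), and fry called none (smallest adjusted p 0.304). With 1 residual degree of freedom camera could hardly call any list that way. The unadjusted camera p of the homeostatic list went from 2.67e-14 to 0.0768, though its estimated correlation was -0.046, below the preset one. These lost calls therefore do not show that the preset calls came from correlated genes.

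These SCI calls rest on 1 residual degree of freedom. The 2 pairs can be split in only 2 ways, too few for a share under 0.05, and the other way called 0 genes against the real 690. Without pool as a factor 0 were called. With the spread pooled over all conditions 0 genes were called. That spread takes in the wider one of EAE (edgeR common dispersion 0.0677, against 0.00643 within SCI microglia). Leaving out either SCI pair left 1 sample per arm, so only log2 changes are given for it. Without the TM2 pair Lpl, Igfbp5, Mmp12, Axl, Ifit3, Ifit1 and Rsad2 had log2 changes of -0.82, -1.44, -1.11, -0.47, 0.68, 0.63 and 0.54, and without the CreTM2 pair -2.73, -4.16, -2.51, -1.10, 1.86, 1.60 and 2.43, so the TM2 pair carried the larger part of these changes. DESeq2 called 195 genes, without Lpl, Axl, Mmp12, Igfbp5, Ifit3, Ifit1 and Rsad2 (adjusted p 0.357, 0.223, 0.159, 0.283, 0.393, 0.33 and 0.749) and without Trem2 itself (0.0828), at log2 changes of -1.77, -0.78, -1.80, -2.78, 1.28, 1.12, 1.496 and -1.49. The clusters of SCI microglia differed by genotype. Cluster 1, led by Lpl, Igf1 and Spp1, held 61.5% of WT and 30.4% of TM2 microglia, and 56.9% of Cre and 39.7% of CreTM2. Cluster 3, led by Egr1, Adamts1 and Atf3, held 20.5% of WT and 30.9% of TM2 microglia, where it was the largest, and 29.2% of Cre and 39.3% of CreTM2. Without the cells of cluster 3 the count was 185 genes, and without those of cluster 8 it was 329. Without cluster 3 Lpl, Igfbp5, Axl and Rsad2 lost their call with log2 changes of -1.63, -2.24, -0.66 and 1.67 (adjusted p 0.0824, 0.0563, 0.0532 and 0.0716), near those with all cells, so these lost calls do not show that the changes came from cluster 3. In the SCI CreTM2 pair sex-linked genes also moved, with a median log2 ratio of 0.55.

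In EAE microglia no gene was called in 11641 (edgeR, 2 pairs), 73 had an unadjusted p under 0.05, and DESeq2 called 0. The other way of splitting the 2 pairs called 156. Trem2 had a log2 change of -0.88 (SE 0.356, adjusted p 1.0) and Lpl one of -0.87 (SE 0.390). The resting marker P2ry12 went from 490 to 462 CPM in the TM2 pair and from 396 to 1124 CPM in the CreTM2 pair. EAE Cre microglia lay mostly in cluster 5 (67.4%) and EAE CreTM2 microglia mostly in cluster 3 (56.5%). In that pair the immediate early genes had a median log2 ratio of 0.78, and the median count per cell was 7590 in Cre and 4809 in CreTM2. The log2 ratios of the EAE pairs correlated at -0.559 across 5742 genes (Pearson), and those of the SCI pairs at 0.65, where genes are not independent replicates. Leaving out either EAE pair left 1 sample per arm, with a spread taken from the naive and SCI pairs alone. The spread within those was narrower (edgeR common dispersion 0.00412 in naive and 0.00643 in SCI, against 0.0677 in EAE). No count of genes is therefore given for those fits. The self-test of the fit with both EAE pairs recovered 20% of genes with simulated 2-fold changes and 95% of those with 4-fold changes. Camera called 9 lists and none held with an estimated correlation (0.864 or more). The phagocytosis median was 0.01 and its mean -0.12.

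The difference of the Trem2 effect between SCI and EAE was tested as an interaction. In microglia it called 0 of 12255 genes with edgeR, and 156 had an unadjusted p under 0.05. The cytokine genes Cxcl1 and Il1b, called in SCI and not in EAE, had edgeR interaction log2 values of 1.16 (SE 0.245) and 1.12 (SE 0.399), EAE less SCI, each with an adjusted p of 1.0. For Spp1 and Ifit3 the edgeR values were 0.68 (SE 0.467) and -1.43 (SE 0.413), with the same adjusted p. In monocytes and macrophages the interaction called 0 genes, with 128 at an unadjusted p under 0.05.

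In SCI monocytes and macrophages edgeR called 5 of 11655 genes between the Trem2-deficient and the control genotypes, and the other way of splitting the 2 pairs called 31. Crybb1, Slc2a5 and Siglech, which mark resting microglia, rose by 1.37 (SE 0.145), 1.33 (SE 0.158) and 0.78 (SE 0.102) on the log2 scale, with adjusted p of 0.0128, 0.0222 and 0.0324. Crybb1 averaged 7.40 ± 3.18 CPM in controls and 19.5 ± 10.2 in the others (SD, n = 2). Siglech moved in the same direction in the microglia of each SCI and EAE pair. In the EAE TM2 and CreTM2 pairs its log2 ratios were -1.49 and 1.516 in monocytes and macrophages, and -0.509 and 1.378 in microglia. RNA of microglia, or microglia placed in this class, may thus account for the rises of resting genes, which was not tested. Tnfsf9, a costimulatory ligand gene, fell from 143 ± 15.9 to 82.4 ± 15.5 CPM (log2 change -0.82, adjusted p 0.0222). Jchain, a plasma cell gene outside the naming rule and named after its values were seen, had a log2 change of -4.25 (SE 0.446, adjusted p 0.0128). With the spread pooled over the conditions, or without pool as a factor, 0 genes were called. Leaving out either pair left 1 sample per arm, so no count is given for it. Thinning to equal depth also left 0 genes. There Crybb1, Siglech, Slc2a5 and Tnfsf9 had log2 changes of 1.13, 0.82, 0.96 and -0.46 (edgeR adjusted p 0.786, 0.786, 0.978 and 0.962). DESeq2 called 3. Trem2 in these cells had a log2 change of -0.996 (SE 0.293, adjusted p 0.548), with log2 ratios of -1.85 in the TM2 and -0.11 in the CreTM2 pair, so these calls are not tied to loss of the transcript in both pairs.

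In EAE monocytes and macrophages edgeR called 0 of 12216 genes, with 70 at an unadjusted p under 0.05, and DESeq2 called 0. The other way of splitting the 2 pairs called 1200. Leaving out either EAE pair left 1 sample per arm and a spread from the SCI pairs alone, so no count of genes is given for it. Trem2 had a log2 change of -0.34 (SE 0.235) and Tyrobp of 0.07 (SE 0.288). In SCI and in EAE camera called 8 of 16 lists with its preset correlation and 0 with an estimated one (smallest adjusted p 0.626 and 0.744), and fry called 0. Of 20 interferon genes 13 rose and 1 fell in SCI when adjusted over the list alone, and none was called over all genes. Median and mean of alternative activation differed in sign in SCI (-0.06 and 0.05) and in EAE (0.14 and -0.19).

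The constitutive and the Cx3cr1CreER-driven loss were compared as another interaction over the SCI and EAE pairs. In microglia edgeR called 0 genes with 637 at an unadjusted p under 0.05, and in monocytes and macrophages 0 with 845. The edgeR interaction value of Trem2, the CreTM2 less the TM2 effect, was 1.04 on the log2 scale in monocytes and macrophages (SE 0.413, adjusted p 0.705). In microglia the edgeR value was 0.41 (SE 0.514, adjusted p 0.864). The log2 ratios of the naive TM2 and CreTM2 pairs correlated at 0.31 across 5742 genes, which are not independent replicates. Cx3cr1 was also lower in CreTM2 than in Cre microglia (log2 ratios of -0.83 in naive, -0.76 in SCI and -0.20 in EAE samples), so effects in the CreTM2 pairs may not come from Trem2 loss alone.

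**Figure D3:**
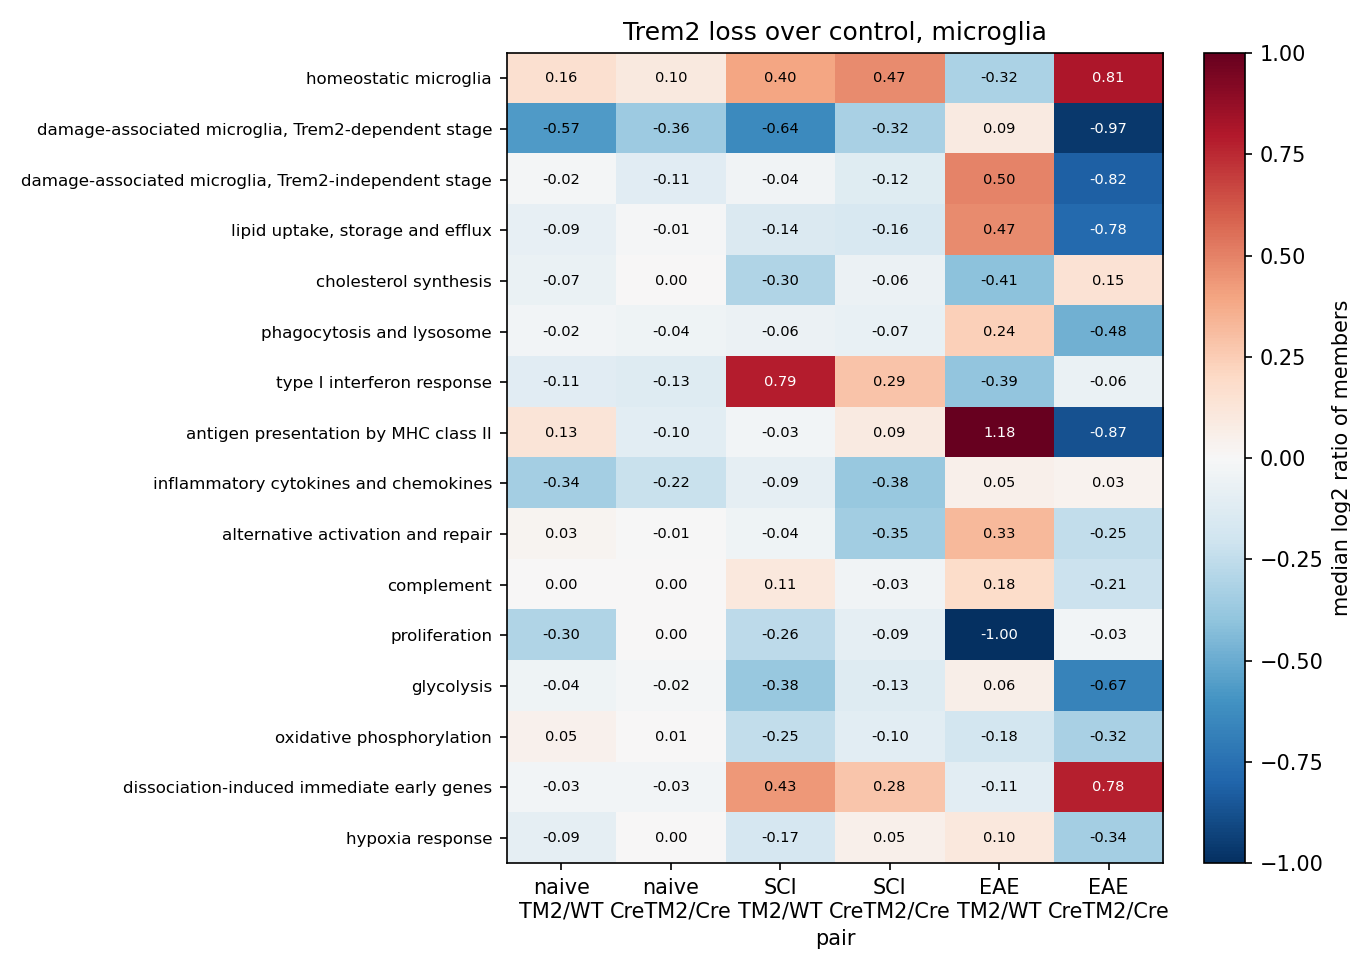
Median log2 ratio of Trem2-deficient over control microglia (colour and printed value) for each gene list (y axis) in each of the 6 pairs (x axis), with 5 CPM added to each level. The Trem2-dependent damage-associated list is negative in 5 of 6 pairs, from -0.97 to -0.32, and 0.09 in the EAE TM2 pair.

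SCI and EAE were then compared directly, since both were mixed in pools B and C, with 4 pairs matched by genotype. In microglia 921 genes were higher and 996 lower in SCI among 12255 tested (edgeR). Igf1, a growth factor gene, averaged 652 ± 177 CPM in SCI and 131 ± 45.7 in EAE (SD, n = 4), a log2 difference of 2.42 (SE 0.223, adjusted p 0.000729). Spp1, Gpnmb and Apoe differed by 2.31, 2.23 and 1.65 on the log2 scale, and the repair-associated genes Folr2 and Mrc1 by 2.55 and 1.58. Folr2 and Mrc1 also mark border-associated macrophages, which made up 1.58% to 4.84% of the SCI samples. They made up 0.178% to 0.434% of EAE WT, TM2 and Cre and 4.56% of EAE CreTM2. RNA or doublets of those cells were not told apart from a change in microglia. Ctla2a, a protease inhibitor gene, Npy, which codes for a neuropeptide, and the chemokine gene Cxcl1 differed by 2.60, 2.74 and 2.05. Cd74, the MHC class II chaperone gene, averaged 385 ± 97.3 CPM in SCI and 4172 ± 3230 in EAE, a log2 difference of -2.96 (SE 0.589, adjusted p 0.0141). H2-Aa, Cxcl9 and the nuclease gene Dnase1l3 differed by -2.80, -3.91 and -4.27. The cell cycle genes Top2a and Ccnb1 differed by -2.94 and -3.14, but the class kept cycling cells unevenly. Cluster 17, led by Top2a and Mki67 and kept as microglia, held 1.28% to 8.57% of the EAE and 0.228% to 0.638% of the SCI samples, while cluster 18, led by Top2a and Stmn1 and left out of every class, held 1.77% to 8.46% of the SCI and 0.249% to 0.734% of the EAE samples. No fit with cluster 18 was run, so lower cell cycle genes in SCI microglia may come from this choice.

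Ctla2a, Npy, Cxcl9 and Dnase1l3 were named for the same direction in 4 of 4 pairs, so their agreement is no evidence. Trem2 and Tyrobp, named in any case, moved the same way in 4 of 4 pairs, with log2 differences of 0.91 (SE 0.234, adjusted p 0.036) and 0.93 (SE 0.155, adjusted p 0.00695). Trem2 lost its call without the WT, the Cre or the CreTM2 pair, at log2 differences of 0.676, 0.954 and 0.83 (edgeR adjusted p 0.148, 0.107 and 0.0878). It also lost it without the pair factor, at 1.03 (0.17). Tyrobp lost its call without the WT pair, at 0.86 (0.052). Cd74 lost its call without the WT or the Cre pair, at -3.324 and -2.571 (0.0504 and 0.0709). H2-Aa lost its call without the WT, TM2 or Cre pair, at log2 differences of -3.215, -2.067 and -2.327 (edgeR adjusted p 0.0949, 0.0613 and 0.142). All these differences kept their sign, so a lost call here does not show a lost difference. The gene count was 820 without the WT pair and 993 without the Cre pair. Cluster 5, led by C4b and Cxcl10, held most microglia of EAE WT (52.2%), TM2 (75.0%) and Cre (67.4%), while cluster 3 held most of EAE CreTM2 (56.5%).

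Of the lists in microglia, 9 of 10 MHC class II genes, 16 of 19 proliferation genes, 9 of 21 inflammatory genes (2 were higher), 6 of 16 cholesterol synthesis genes, 4 of 20 interferon genes and 3 of 16 glycolytic genes were lower in SCI. Of 20 lipid genes 13 were higher and 1 lower, and 11 of 19 Trem2-dependent, 5 of 8 Trem2-independent (1 was lower), 11 of 24 phagocytic and lysosomal and 5 of 17 alternative activation genes were higher. Among homeostatic genes 2 were higher and 1 lower, with a median of -0.04 and a mean of 0.08. Complement had 2 higher and 3 lower, with a median of 0.10 and a mean of -0.67. Oxidative phosphorylation and immediate early genes had 1 and 2 higher, and hypoxia genes 1 higher and 1 lower. Adjusted over the list alone the MHC class II, proliferation and lipid counts were 10, 17 and 13. Camera called 11 of 16 lists, none of which held with an estimated correlation (0.289 or more), and fry called cholesterol synthesis and proliferation (adjusted p 0.0255 for each). The proliferation values share the limit of clusters 17 and 18.

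In monocytes and macrophages 2259 genes were higher and 2406 lower in SCI among 12129 tested (edgeR, 4 pairs). In the 2 pairs of pool C the SCI samples, and hardly the EAE samples, held cells with Y-linked counts (23.7% and 40.2% against 3.98% and 5.66% at 3000 counts), so sex moves with condition there. Mfge8, a bridging gene for the uptake of dying cells, averaged 663 ± 236 CPM in SCI and 53.2 ± 14.7 in EAE (SD, n = 4), a log2 difference of 3.60 (SE 0.165, adjusted p 2.81e-05). Cd36, Spp1, Gpnmb and Trem2 differed by 3.13, 2.63, 2.56 and 1.58, Tyrobp by 1.02, and Vsig4, a complement receptor gene at 8.63 CPM in SCI, by 4.41. Nos2, the inducible nitric oxide synthase gene, averaged 8.85 ± 4.53 CPM in SCI and 981 ± 678 in EAE, a log2 difference of -6.61 (SE 0.630, adjusted p 0.000285). Inhba and Ly6i, genes of inflammatory monocytes, differed by -6.54 and -6.12. H2-Ab1, Cxcl9, Ccl5 and Il6 differed by -4.21, -5.40, -4.65 and -4.68. The glucose transporter gene Slc2a1, the glycolytic gene Pgk1 and the growth factor gene Vegfa differed by -2.10, -2.04 and -1.91. Mfge8, Vsig4, Nos2, Inhba and Ly6i were named for the same direction in 4 of 4 pairs, which Trem2 and Tyrobp, named in any case, also had.

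All 10 MHC class II genes, 15 of 16 glycolytic, 15 of 20 interferon, 15 of 21 inflammatory and 9 of 12 hypoxia genes were lower in SCI in these cells. Of 16 cholesterol synthesis genes 13 were lower and 1 higher. Of 24 phagocytic and lysosomal genes 17 were higher and 1 lower, of 20 lipid genes 14 and 1, of 19 Trem2-dependent genes 11 and 4, and of 8 Trem2-independent genes 5 and 3. Homeostatic genes had 10 higher and 2 lower, alternative activation 5 and 7, complement 5 and 6, proliferation 2 and 4, oxidative phosphorylation 2 and 3, and immediate early genes 4 and 1. Adjusted over the list alone 15 cholesterol synthesis genes were lower and 20 phagocytic genes higher. Camera called 11 lists and none held with an estimated correlation (0.136 or more), while fry called 13 (smallest adjusted p 0.0024). Cluster 4, led by Gpnmb and Spp1, held 69.0% to 83.4% of these cells in the SCI samples, and cluster 2, led by Tgfbi and Il1b, 32.0% to 50.8% in the EAE samples. Without cluster 4 the count was 2434 genes, and Mfge8 and Tyrobp lost their call with log2 differences of 0.07 and 0.29 (adjusted p 0.858 and 0.0652).

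**Figure D4:**
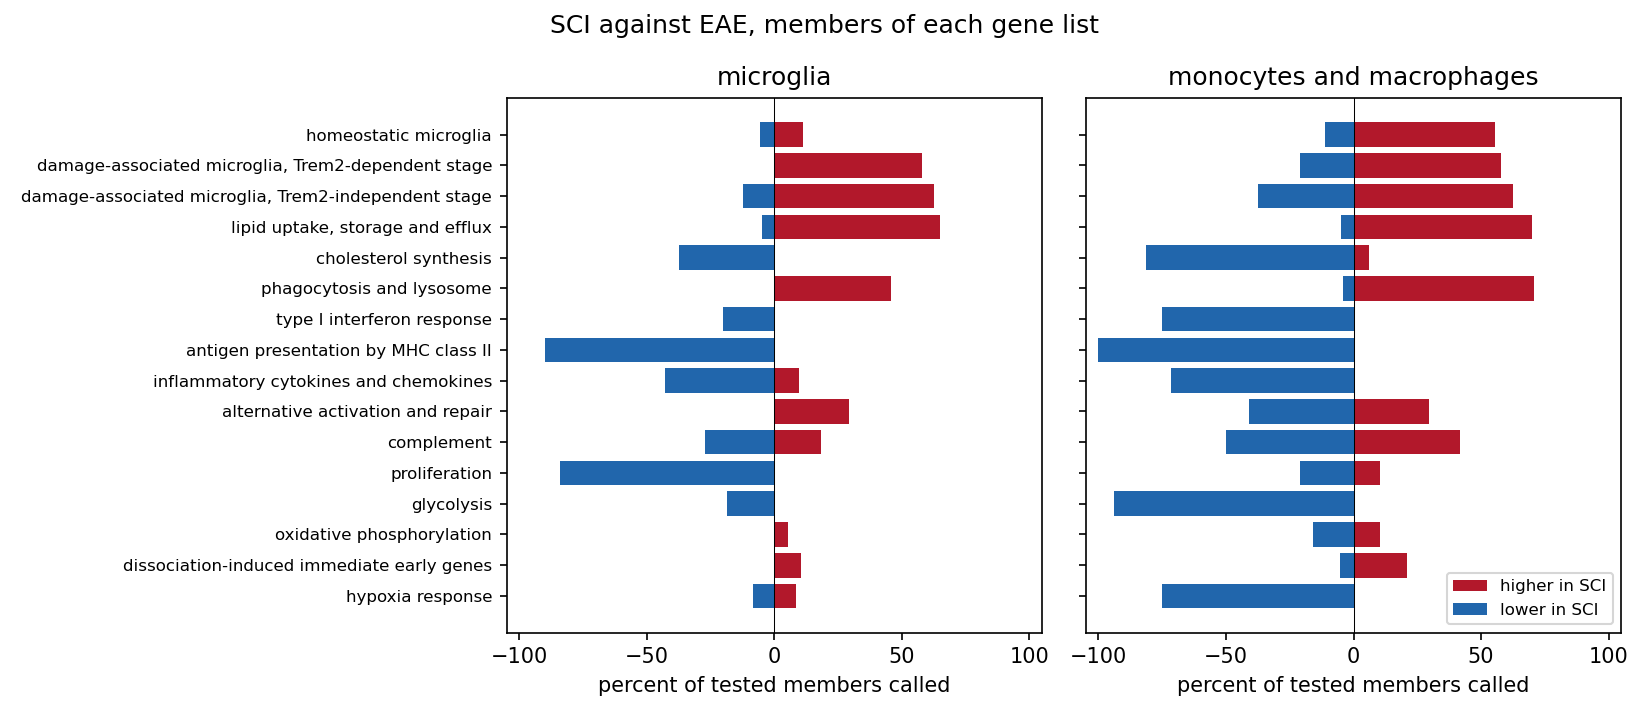
Percent of the tested members of each gene list (y axis) called higher in SCI (red, to the right) or lower in SCI (blue, to the left), for microglia and for monocytes and macrophages. The bar for MHC class II genes stands for 9 of 10 members lower in microglia and 10 of 10 lower in monocytes and macrophages.

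Each condition was also set against naive microglia in the WT and TM2 samples, where pool and condition cannot be told apart because naive cells were in pool A alone. The class also lay in different clusters, in clusters 0 and 8 in naive WT (65.6% and 31.9%), in 1 and 3 in SCI WT (61.5% and 20.5%) and in 5 and 17 in EAE WT (52.2% and 24.4%). SCI against naive gave 2676 genes higher and 2377 lower of 11937 (edgeR, 2 pairs by genotype). Spp1 averaged 6381 ± 2964 CPM in SCI and 8.92 ± 10.04 in naive cells (SD, n = 2), a log2 difference of 9.80 (SE 0.711, adjusted p 5.95e-05). Gpnmb, a lysosomal gene, Igf1 and Apoe differed by 12.39, 7.95 and 6.06, the interferon gene Rsad2 by 5.31, and the cell cycle gene Mki67 by 2.64. A difference as large as 12.39 leaves hardly any Gpnmb counts in naive cells, so its exact size means little. P2ry12 and Siglech were lower, by -2.14 and -2.19, and Tyrobp and Trem2 were higher, by 1.23 and 1.12 (adjusted p 0.00189 and 0.0466). With DESeq2 the adjusted p of Trem2 was 0.206. All 20 interferon genes, 18 of 19 Trem2-dependent, 17 of 20 lipid, 17 of 21 inflammatory and 19 of 24 phagocytic genes were higher, and 16 of 18 homeostatic genes lower, with the same 20, 18, 17, 19 and 16 when adjusted over the list alone, where the inflammatory count was 18.

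EAE against naive gave 3091 genes higher and 2639 lower of 11937. The chemokine gene Cxcl10 averaged 1713 ± 328 CPM in EAE and 40.7 ± 12.3 in naive microglia (SD, n = 2), a log2 difference of 5.54 (SE 0.248, adjusted p 8.82e-06). Cxcl9, Ccl5, the complement gene C4b and the costimulatory receptor gene Cd40 differed by 9.20, 7.99, 7.95 and 5.33, Spp1 by 7.29, Apoe by 4.57 and Mki67 by 4.41, and P2ry12 by -2.59. Trem2 (0.40, adjusted p 0.437) and Tyrobp (0.37, adjusted p 0.145) did not pass. All 20 interferon and all 10 MHC class II genes, 18 of 19 proliferation and 18 of 21 inflammatory genes were higher, and 16 of 18 homeostatic genes lower, with the same counts when adjusted over the list alone. Camera called 14 lists in SCI and 15 in EAE against naive, none with an estimated correlation (0.332 and 0.272 or more), and fry called 9 and 13 (smallest adjusted p 0.0469 and 0.0451).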

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

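Of the tests below, the one of cells with a wrong tag was written before its result was seen, and all others were chosen only after the result was seen. A search for samples apart from their group with Dixon's test over 57 groups found 10, where chance alone gives about 1 in 20 groups. A search for opposite directions between 2 conditions or between the 2 lines, over 120 comparisons, found 11. With so few pairs per group opposite signs also arise by chance, and no chance rate was worked out. None of those differences was tested, so the 11 are no evidence of an effect by themselves.

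Cx3cr1 was lower in CreTM2 than in Cre microglia, from 4078 to 2296 CPM in naive, from 1738 to 1028 CPM in SCI and from 1614 to 1401 CPM in EAE samples (log2 ratios -0.827, -0.755 and -0.203). Relative to the other homeostatic genes its log2 ratio averaged -1.083 over the 3 CreTM2 pairs, and lay between -0.276 and 0.177 in the TM2 pairs. In naive and SCI samples this is near the size that 1 lost copy would give, so CreTM2 cells may carry the CreER insertion in Cx3cr1 where Cre cells do not, while the EAE pair reaches it only relative to other homeostatic genes, whose median rose by 0.858. A fall of homeostatic genes as a whole was excluded in the naive and SCI pairs, where their median was 0.109 or more. Depth was excluded there, since the ratio at 3000 counts was -0.783 or lower, and the EAE pair (-0.246) was not part of these tests, while in monocytes and macrophages the CreTM2 pairs had -0.696 in SCI and 0.356 in EAE and the EAE TM2 pair -0.678, where 0.356 is not what 1 lost copy would give, so this explanation stays open.

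Treml1, which begins 5769 bases past the end of Trem2, was higher in CreTM2 than in Cre microglia (17.2 against 4.76 CPM in naive samples). Counting error was excluded, since the intervals were apart in 3 of 3 pairs. Loss of Trem2 transcript alone was excluded in microglia, where the highest thinned ratio of the TM2 pairs was 0.291. A change at the recombined locus could account for it, with a lowest thinned log2 ratio of 1.58 in microglia and ratios of 0.748 and -0.776 in monocytes and macrophages, though there the EAE TM2 pair had 1.363, so for those cells the question stays open. The edgeR quasi-likelihood interaction for Treml1 was 2.03 (adjusted p 0.81).

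Y-linked genes, measured to check the pools, had a count at 3000 counts per cell in 23.72% of SCI Cre and 40.18% of SCI CreTM2 cells, in 3.975% of EAE Cre and 5.655% of EAE CreTM2 cells, and in at most 0.554% elsewhere. The SCI samples of pool C thus held male cells, so in pool C sex moves with condition, in 2 of the 4 SCI and EAE pairs, and with genotype in SCI, where Xist was found in 44.3% of Cre and 16.09% of CreTM2 cells. In the EAE samples, cells with 2 Y-linked counts or more were 22.17 and 11.09 times as frequent in clusters 1 and 4, the main SCI clusters, as in other clusters (10.83 and 6.306 times for 1 count or more at 3000 counts per cell), so some of these cells may be SCI cells that carry an EAE tag. Evenly spread free RNA was not decided (observed cells were 4.373 and 6.365 times a Poisson spread). Male EAE animals stay open as a source, since at least 50% of those cells had Xist, but so did 32.68% and 16.77% of such cells in SCI Cre and SCI CreTM2, so an Xist count does not mark a cell as female.

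For the counts of genes called with Trem2 loss, regrouping the samples decides nothing, since a real count of 0 is reached by every grouping (100 of 100 in microglia and 32 of 32 in monocytes and macrophages). The highest other groupings called 696 and 649 genes, and each parted the members of only 2 pairs. With pair kept as a factor, such a grouping compares the deficient and control samples of those 2 pairs alone, in the same or opposite directions. These counts thus point to no further structure of the samples, and which pairs they parted was not worked out. Regroupings within pairs called at most 79 and 0. For SCI against EAE 1 of 32 groupings, the real one, gave as many as 1917 genes in microglia and 4665 in monocytes and macrophages, and the highest other gave 0. Most of those groupings break the pairs, and within pairs only 8 are possible, too few for a share under 0.05, again with 0 as the highest other count.

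Samples apart were naive CreTM2 in neutrophils (2.427%, nearest 1.073%), naive TM2 in lymphocytes (0.6965%, nearest 0.1302%) and in median counts (4865, nearest 4209). In EAE they were CreTM2 in border-associated macrophages (4.563%, nearest 0.4341%) and in median counts (4809, nearest 7590), and Cre in lymphocytes (16.14%, nearest 3.107%). Among pair differences they were EAE CreTM2 in microglia (44.66 points) and lymphocytes (-13.49 points), and EAE TM2 in unnamed cells (-22.31 points) and in the proliferation median (-0.999).

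The search for opposite directions with Trem2 loss gave values whose difference was not tested. Among class shares they were monocytes and macrophages between SCI and naive (a difference of -2.69 points) and dendritic cells between EAE and naive (-4.087). Lymphocytes between SCI and EAE (8.493) and other cells between SCI and naive (-1.674) were the others. Among list medians in microglia they were interferon between SCI and EAE (0.766) and SCI and naive (0.657), inflammatory genes between SCI and EAE (-0.275) and EAE and naive (0.3215), oxidative phosphorylation between SCI and naive (-0.203) and EAE and naive (-0.2785), and immediate early genes between SCI and naive (0.3845).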

How the results depend on the processing

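Of 1152 values under alternatives, from 114 pairings of a named gene with a comparison, 954 kept their state, called or not called. A call was lost in 166, gained in 32 and reversed in 0, and the cause was not tested. The 954 include values uncalled in both fits. For loss over all pairs these were 106 in microglia and 54 in monocytes and macrophages, and within EAE 40 and 18. In SCI microglia 101 values lost their call, 63 of them under pooled spread and 21 without the pool as replicate block. Counts of genes called changed as follows. Without a filter on low counts Trem2 loss called 350 in microglia, 62 in monocytes and macrophages, 195 in naive, 1043 in SCI and 11 in EAE microglia, 171 in SCI and 6 in EAE monocytes and macrophages. The same alternative gave 20 for the condition interaction in monocytes and macrophages, and 381 and 429 for the line interaction. DESeq2 called 29, 1, 15, 195 and 3 for loss in microglia, in monocytes and macrophages, in naive and SCI microglia, and in SCI monocytes and macrophages. The CreTM2 pairs alone gave 1 in monocytes and macrophages. Without the replicate block both SCI counts were 0, and with the pair as replicate block the naive count was 58.

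With each pair left out, loss in microglia called 0 to 66. Within conditions this left 1 sample per arm, so the spread was pooled and the lone sample is assumed to vary like the other groups. It gave 0 to 0 in naive and in SCI, 756 to 1843 in EAE microglia and 199 to 740 in EAE monocytes and macrophages. Pooled spread with all pairs gave 0 in naive microglia and both SCI classes. SCI against EAE in microglia gave 820 without the WT, 993 without the Cre and up to 1568 without another pair, and 750 in WT and Cre alone, and in monocytes and macrophages 1642 in WT and Cre alone and 2434 without cluster 4. SCI microglia gave 185 without cluster 3, 329 without cluster 8 and 455 without the 5% of cells with most counts. SCI monocytes and macrophages gave 0 without those cells and 0 after thinning, and EAE ones 1 after thinning.

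The Trem2-dependent list median in microglia averaged -0.4605 over the 6 pairs, -0.5173 and -0.38 with offsets of 1 and 20 CPM, and -0.2235 as a difference of mean log counts per cell, where the naive pairs had -0.026 and -0.037 and the EAE TM2 pair -0.009. With an estimated correlation 0 lists were called in all 11 comparisons. These tests had 1 to 5 residual degrees of freedom, so this count alone does not show that the preset calls came from correlated genes. Among shares, microglia ranged from -5.557 to 6.8 points without a pair, monocytes and macrophages from -8.15 to 8.535 (-4.326 with the other denominator), lymphocytes from -2.889 to 0.03151 and other cells from -0.1018 to 0.4483. The share test without doublets was not run, as none were called, and leaving out a genotype against naive leaves no residual degrees of freedom. The block moved no other count by over 1.5 times. Naive samples had the fewest counts, from 8443187 in CreTM2, which limits what low genes can show there.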

Other observations

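No further test was added here, so none was chosen after a result was seen beyond those above. Dendritic cells made up 4.73% of EAE WT, 1.64% of EAE TM2, 7.06% of EAE Cre and 2.10% of EAE CreTM2 cells, and at most 0.0995% of naive samples. Lymphocytes made up 3.11%, 1.14%, 16.1% and 2.65% of the same EAE samples and 0.437% to 3.30% of the SCI samples. A microglial cluster led by the interferon-induced genes Ifit3, Ifit2 and Rsad2 held 2.02% of SCI WT and 4.995% of SCI TM2 cells, and 5.87% of SCI Cre and 7.70% of SCI CreTM2 cells, but 2.54% of EAE WT, 0.782% of EAE TM2, 0.525% of EAE Cre and 2.47% of EAE CreTM2 cells. A microglial cluster led by Top2a and Mki67 held 8.57% of EAE WT, 1.28% of EAE TM2, 1.30% of EAE Cre and 5.46% of EAE CreTM2 cells. Another cluster with these genes, left out of every class, held 8.46% of SCI WT, 2.69% of SCI TM2, 3.36% of SCI Cre and 1.77% of SCI CreTM2 cells.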
